A study of Mus musculus with 8 samples.

How the data were processed

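RNA-seq was measured in cultured mouse hippocampal neurons in 8 samples, 2 in each of 4 groups. Per the labels' protocols, neurons at 9 days in vitro (DIV) received adeno-associated virus of serotype 2/9 at 1500 genomic copies per cell for 12 hours, with a synapsin promoter. From 10 DIV they received Accell siRNA, a chemically modified siRNA taken up without a transfection reagent, for 4 days, and RNA was collected at 14 DIV. The control group carried EGFP and non-targeting siRNA, and the knockdown group carried EGFP and siRNA against Rbfox1 and Rbfox3. The 2 rescue groups carried the same siRNA and a Flag-tagged Rbfox1 splice isoform, cytoplasmic or nuclear, marked siMt in the labels, which is read here as mutated at the siRNA sites. Per the labels' protocols, ribosomal RNA was removed, libraries were made with TruSeq without strand information, and reads were paired-end of 50 nt. Nothing in the labels says whether the samples of a group came from separate cultures, so any spread between them may be technical. The p-values for genes rest on the authors' errors. Those for exons, junction reads and gene lists do not measure the spread between samples.

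Per the submitters' processing notes, CASAVA and Cufflinks were used with the mouse build mm9, and their versions are not given in the sources used here. The authors deposited 3 expression tables and 3 splicing tables, each comparing a pair of groups. The expression tables hold 1 FPKM value per group, fragments normalised to transcript length and library size, so that the libraries of a group are already combined by the authors. The authors' deposited log2 fold change, test statistic, p-value and q-value stand beside each gene. The splicing tables hold cassette exons only, called with SpliceTrap per the file names. They give a deposited inclusion fraction per group, a deposited splice change score (the difference of inclusion), the authors' p-value, deposited counts of reads on the skipping junction, counts on the inclusion junctions and the coverage signal of the full isoform. The tables list only exons that the authors called, so exons without a change were not analysed here. Another 30 value columns of the splicing tables, uncorrected or per-exon versions of these measures, were not used here. Library totals were not used here, so sequencing depth per sample is unknown. Per exon, junction reads ranged from 14 to 7808 in a group.

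The deposited log2 fold change equalled that computed from the FPKM values within 2.498e-04. The p-value equalled the two-sided normal tail of the test statistic. The standard error on the log2 scale was therefore taken as the fold change divided by the test statistic, and is called the implied error. The knockdown FPKM was identical in the 3 tables, and the q for a given p was alike in the 3 tables, so q was adjusted over the comparisons together. The authors' p for exons behaved as a normal tail with 1 fixed spread per table, with a median of 0.0215 in the knockdown table, and so takes no account of read number. Locus starts in the expression tables were counted from 0, because 3611 spans equalled the gene's RefSeq length that way and 320 the other way. Starts are printed from 1, and all printed positions are mm9.

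Calls were the authors' own, q below 0.05. The planned test on values per library could not be run because the tables hold group values. Genes were called reversed when they passed q 0.05 in the knockdown and in a rescue table with opposite sign. Because both tables share the knockdown values, opposite changes arise without any effect. Such unchanged groups were simulated 100 times, with 50% of the smaller squared implied error given to the knockdown group, and again with all of it. That simulation used genes with an implied error under 1, a limit chosen after the values were seen, because a few microRNA and snoRNA genes had very large errors. It also left out Rbfox1 and genes below 1 FPKM in every group. The rescues were compared by a z test of the difference of their fold changes, with Benjamini-Hochberg adjustment. On simulated data with 14793 genes and 200 changed, that test recovered 69% of genes changed by 1 on the log2 scale and 94% of those changed by 2, with 0 false calls. These genes too had an implied error under 1. Of the unchanged genes 0.644% had an unadjusted p below 0.05, where an exact test gives 5%, so the test is conservative.

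Gene lists were fixed before the data were examined, 20 in all. For each list the calls, Fisher's exact test (two-sided, adjusted over 60 list and table pairs) and the percentile of the median among 10000 random lists matched on FPKM were computed. The percentiles were not adjusted for the number of lists, and members of a list are not independent. Exons were matched between tables by coordinates, and by coordinates of both neighbouring exons too where all 3 tables or both rescues were compared. Junction reads were compared by Fisher's exact test, which compares the pooled libraries, not the conditions, and intervals are exact Clopper-Pearson at 95% and cover counting error only. Motif tests used the longest 3 prime UTR per gene from GENCODE M21 transcripts, joined by gene name. That annotation is of another build, so none of its coordinates were used, and the planned intron motif test was not run. Named genes followed a rule fixed before the data were examined: the Rbfox genes, the 10 largest rises and falls with FPKM of at least 1, up to 4 called members per list or 2 members as values, the 10 largest exon changes each way, up to 6 exons in known Rbfox target genes and up to 8 reversed exons. The alternatives were q 0.01, an FPKM minimum of 1, q recomputed from p, centring, and minimum inclusion changes. Pseudocounts of 0.1 and 1 with a change of at least 0.5 were others. For gene calls in a table, the FPKM minimum also meant recomputing q over the genes kept. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and ribosomal RNA matches were searched with blastn 2.17.0. Results for some genes are not reported here.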

Results

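The 8 samples fall into 4 groups of 2: control, Rbfox1 and Rbfox3 knockdown, knockdown with the cytoplasmic Rbfox1 isoform, and knockdown with the nuclear isoform. Rbfox proteins are RNA-binding regulators of alternative splicing in neurons. The comparisons ask which transcripts and exons depend on Rbfox1 and Rbfox3, and which of them each isoform restores. Every FPKM below is the authors' value for a group, so no replicate spread can be given. The implied error comes from the authors' test and is not a measured spread between samples. Over genes with FPKM of at least 1 and an implied error under 1, its median was 0.146 (knockdown), 0.155 (cytoplasmic) and 0.157 (nuclear). The log2 changes of these genes spread by 0.156, 0.120 and 0.0936 (scaled median absolute deviation). In both rescues that error was therefore wider than the spread of the changes.

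Rbfox1 (chromosome 16, 5884886 to 7412573) fell from 25.7 FPKM in control to 1.94 in the knockdown group, which is 7.53% of control. Its log2 fold change was -3.73 with an implied error of 0.148 in the authors' deposited table. Rbfox3 (chromosome 11, 118351074 to 118770886) fell from 12.4 to 1.59 FPKM, a log2 fold change of -2.96 in the authors' deposited table. Rbfox2 measured 35.4 and 42.1 FPKM and was not called. Rbfox1 FPKM was 16.1 in the cytoplasmic rescue, 62.5% of control, and 38.2 in the nuclear rescue, 148% of control. The nuclear level was therefore 2.38 times the cytoplasmic level, so isoform and amount of Rbfox1 RNA differ together between the rescues. These values do not separate vector from endogenous RNA. Whether the transcript length used for FPKM applies to the vector RNA is not known, so the percentages of control are uncertain. Rbfox3 stayed at 1.59 and 1.53 FPKM in the cytoplasmic and nuclear rescue.

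**Figure D1:**
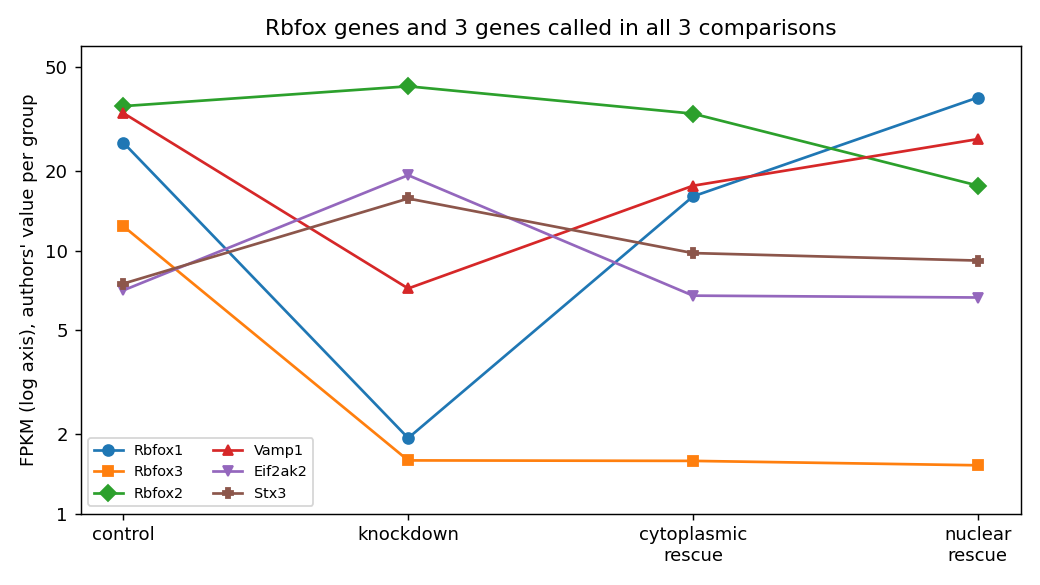
FPKM of 6 genes (log axis, the authors' value per group, no error bars) in the 4 groups. Rbfox1 goes from 25.7 to 1.94 and back to 16.1 and 38.2, while Rbfox3 goes from 12.4 to 1.59 and stays near that in both rescues.

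Knockdown lowered more genes than it raised. Of 15598 genes, 246 fell and 121 rose at q below 0.05, 367 in all. Vamp1, Npy and Nptx2 were among the largest falls, and the myelin gene Mag and the antiviral kinase gene Eif2ak2 among the largest rises. Vamp1, a synaptic vesicle membrane protein gene, fell from 33.3 to 7.18 FPKM, a log2 fold change of -2.22 with an implied error of 0.143 in the authors' deposited table. Neuropeptide Y gene Npy fell from 155 to 38.6 FPKM, and Nptx2, a secreted synaptic pentraxin, fell from 88.8 to 30.1. Eif2ak2 rose from 7.06 to 19.3 FPKM, a log2 fold change of 1.45 in the authors' deposited table. Cxadr, a cell adhesion protein known as a virus receptor, rose from 30.2 to 74.2 FPKM, and Nmb, a neuropeptide gene, from 8.97 to 19.7. Lars2, a mitochondrial leucyl-tRNA synthetase gene, rose from 61.8 to 155 FPKM with an implied error of 0.325. Other large falls were in Arr3, Cryba2, Krt75, Spink2 and Rxfp1, and other large rises in Enpp6, Mag, Ntsr1, Chodl, Ada and Prph. A fold change of 2 or more was seen for 83 of the falls and 17 of the rises, and 314 of the called genes had an FPKM of at least 1 in a group.

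Interneuron markers held 5 called genes of 14 measured. Npy, Cck, Tac1 and Vip fell, with Cck going from 194 to 122 FPKM and Tac1 from 28.0 to 15.9, while Calb2 rose from 90.1 to 171 (Fisher's exact adjusted p = 3.64e-04). Adjusted over the list alone, 7 passed. Activity-regulated genes held 6 called of 27, with Nptx1, Nptx2 and Ptgs2 lower and Npas4, a transcription factor gene induced by neuronal activity, higher at 15.8 against 8.88 FPKM (Fisher's exact adjusted p = 4.92e-04). Adjusted over the list alone, 6 rose and 6 fell. Voltage-gated channel genes held 5 called of 37, 4 of them lower, including Kcnq3 (14.2 to 9.02 FPKM), Scn1a and Scn2b (Fisher's exact adjusted p = 0.0127). GABA signalling genes held 3 falls of 20, Gabrd and Gad2 among them, which did not pass the adjustment (Fisher's exact adjusted p = 0.0667). Synaptic vesicle genes held 2 falls of 35, Vamp1 and Rph3a, but 28 of the 35 lay below 0, with a median log2 fold change of -0.15 at percentile 0 of random lists. Medians also lay low for GABA signalling (-0.14, percentile 0.04), calcium signalling (-0.08, percentile 0.02) and channels (-0.09, percentile 0.01), and those of activity-regulated genes (-0.13) and interneuron markers (-0.27) were at percentile 0. Glutamate receptor genes were at percentile 1.11.

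Markers of other cell types moved too. Of 16 oligodendrocyte lineage markers 4 rose and 1 fell (Fisher's exact adjusted p = 4.92e-04). Mag rose from 0.538 to 1.95 FPKM and Mbp from 11.6 to 22.6, whereas Gpr17, a marker of early lineage cells, fell from 8.60 to 4.12. Of 15 microglia markers 3 fell, C1qa, C1qc and Csf1r (Fisher's exact adjusted p = 0.0323). The median log2 fold change of that list was -0.81, and 10 passed when adjusted over the list alone, all lower. The list did not pass at q 0.01, where C1qa and C1qc lost their calls, or with an FPKM minimum of 1, where Csf1r did because its FPKM is lower (Fisher's exact adjusted p = 0.540 and 0.0586). None of 16 astrocyte markers was called, with Gfap at 569 and 570 FPKM. None of 45 RNA-binding regulators, 14 proliferation genes or 12 vascular genes was called, yet their medians lay high among random lists. Proliferation genes had a median log2 fold change of 0.20 (13 of 14 above 0, Sox2 and Top2a among them, percentile 99.95), RNA-binding regulators 0.11 (33 of 45 above 0, Hnrnpu among them, percentile 99.95) and vascular markers 0.20 (percentile 99.69). The median of the oligodendrocyte lineage list was at percentile 99.98 and that of the microglia list at percentile 0. None of 24 stress genes or 14 reference genes was called, with medians at percentiles 44.29 and 45.66. Of the other lists, interferon genes had 1 call (Eif2ak2), pan-neuronal markers 2 (Dcx higher, Nefm lower), calcium signalling 2 (Atp2b4 higher, Camkk1 lower), glutamate receptor genes 1 (Homer2), autism-related genes 2 (Kcnq3 and Scn1a) and genes with known Rbfox exons 4 (Rbfox1, Rbfox3 and Mef2a among them). At q 0.01 the calls of Cryba2, Homer2 and Mef2a were lost, and with a change of at least 0.5 on log2(FPKM + 1) those of Csf1r, Homer2, Mef2a, Scn1a and Camkk1. The vascular markers had 6 passing when adjusted over the list alone, 5 of them higher.

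**Figure D2:**
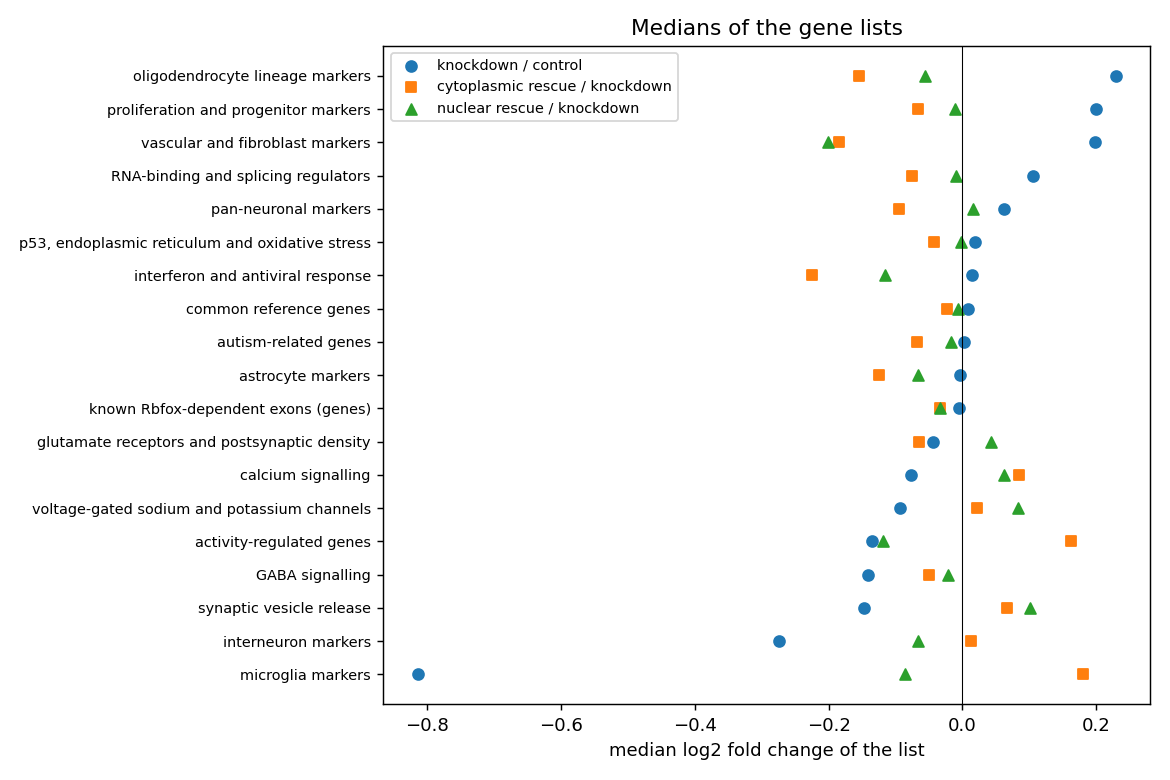
Median log2 fold change (x axis) of each fixed gene list except the Rbfox family (y axis), with 1 marker per comparison and no error bars. The microglia list lies at -0.81 in the knockdown comparison.

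Adding the cytoplasmic isoform raised 52 genes and lowered 27 of 15598. The rises include synaptic and activity-related genes that had fallen in the knockdown. Vamp1 rose from 7.18 to 17.6 FPKM, a log2 fold change of 1.30 in the authors' deposited table, Nptx2 from 30.1 to 48.2 and Npy from 38.6 to 57.0. Ptgs2, an inducible prostaglandin synthase, rose from 13.8 to 27.1 FPKM. Inhba, which was not called in the knockdown, rose from 1.66 to 3.48 FPKM. Eif2ak2 fell from 19.3 to 6.74 FPKM, a log2 fold change of -1.52 in the authors' deposited table. Htr1a, a serotonin receptor gene, fell from 1.45 to 0.665 FPKM, and Chodl, Stx3, Dsp and Fzd7 also fell. Areg, Lipi and Psg28 were among the other large rises. Activity-regulated genes held 3 rises of 27 (Ptgs2, Inhba and Nptx2), and 1 of the 20 lists, this one, passed in this comparison (Fisher's exact adjusted p = 0.00408). Single members were called in the lists of synaptic vesicle genes (Vamp1), calcium signalling (Camkk1), channels and autism-related genes (Kcnq3), interneuron markers (Npy), interferon genes (Eif2ak2), stress genes (Herpud1) and vascular markers (Kdr). Rbfox1 was the 1 call in the Rbfox family and in the genes with known Rbfox exons, and the other lists had 0. With q 0.01, and with q recomputed from p in this comparison alone, the calls of Npy, Kcnq3, Herpud1, Kdr, Krt75, Ntsr1, Areg, Psg28 and Sema4f were lost, and at q 0.01 that of Lipi too. A change of at least 0.5 on log2(FPKM + 1) was missed by Kcnq3, Kdr, Krt75, Ntsr1, Psg28, Sema4f, Dsp and Fzd7. In the interferon list no member besides Eif2ak2 was called, but the median log2 fold change was -0.23 against -0.08 for random lists, at percentile 0. That list had not risen in the knockdown, where its median was 0.01 at percentile 37.2, with 19 members above and 19 below 0. In the cytoplasmic rescue, medians at percentile 100 were seen for activity-regulated (0.16), synaptic vesicle (0.07) and calcium signalling genes (0.08). Channels (0.02) were at percentile 99.92 and microglia markers (0.18) at percentile 99.9. Astrocyte (-0.13), vascular (-0.18) and oligodendrocyte lineage markers (-0.15) were at percentiles 0.77, 1.085 and 1.72, with Gfap at 570 and 477 FPKM. The random lists do not account for the shared knockdown values. Opposite list medians in the knockdown and a rescue can therefore arise without any effect. No microglia, oligodendrocyte or astrocyte marker was called, with C1qa at 1.97 and 2.55 FPKM.

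In total 26 genes were called in both tables, all in opposite directions, 14 down then up and 12 up then down. Independent lists would share 1.005 in opposite directions. Unchanged groups that share the knockdown values gave a mean of 0.21 and at most 2, and at most 9 when all of the smaller error was given to the knockdown group. Without Rbfox1, which the vector supplies, 25 remained, among them Penk, Kcnq3, Camkk1, Syt12 and Cabp7 (down then up) and Ntsr1, Chodl and Efnb3 (up then down). Across genes, the covariance of the fold changes was -0.0163, against simulated values of -0.0157 and, with the larger share, -0.0313. Both rest on the implied errors and on an assumed share of them. In the nuclear rescue, which shares the same knockdown values, the same settings gave more negative covariances than were seen. The nearness of -0.0163 to -0.0157 therefore does not show that the shared values account for it. How much of the negative relation comes from the shared knockdown values is not known, and part of the excess of reversed genes may come from them.

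With the nuclear isoform 11 genes rose and 6 fell of 15489. Vamp1 rose from 7.18 to 26.5 FPKM, a log2 fold change of 1.89 in the authors' deposited table. 6330527O06Rik rose from 1.80 to 5.27 FPKM, and Eif2ak2 fell from 19.3 to 6.63. Rbfox2 fell from 42.1 to 17.7 FPKM, a log2 fold change of -1.25 in the authors' deposited table, against an uncalled change from 42.1 to 33.2 in the cytoplasmic rescue. Stx3, Npas4, Lats1 and Tmem2 were lower, and Sema4f, Pcnxl2, Iyd and Gm20594 higher. An unadjusted p below 0.05 was listed for 162 genes, 1.05% of those listed where chance alone gives 5%. The share was 5.33% in the cytoplasmic and 10.9% in the knockdown table. A share under 5% means that the authors' test was conservative here, so the few calls do not show that few genes changed. The calls of Sema4f and Pcnxl2 were lost at q 0.01, with q recomputed from p and with a change of at least 0.5 on log2(FPKM + 1). In the lists of the Rbfox family and of genes with known Rbfox exons, Rbfox1, which the vector supplies, and Rbfox2 were called, so besides Rbfox1 each held 1 call. Single members were called among synaptic vesicle genes (Vamp1), activity-regulated genes (Npas4) and interferon genes (Eif2ak2), and the other lists had 0. The interferon list had a median log2 fold change of -0.12 against -0.03 for random lists, at percentile 0.15. Synaptic vesicle (0.10), channel (0.08) and calcium signalling genes (0.06) had medians at percentile 100, and glutamate receptor genes (0.04) at percentile 99.92. Activity-regulated genes (-0.12) were at percentile 0, vascular markers (-0.20) at percentile 0.02 and astrocyte markers (-0.07) at percentile 0.74. Here too the random lists do not account for the shared knockdown values, so medians opposite to those in the knockdown can arise without any effect.

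Of the 10 genes called in both the knockdown and nuclear tables, all changed in opposite directions, against 0.203 for independent lists and at most 3 in the simulation (9 with the larger share). Without Rbfox1 the count is 9, and part of any excess may come from the shared knockdown values. Besides Rbfox1 these are Vamp1, Hipk4, Morc2b, Cd5l, 6330527O06Rik and Pcnxl2 (down then up) and Npas4, Stx3 and Eif2ak2 (up then down). Hipk4, Morc2b and Cd5l lie below 1 FPKM in every group and drop out with an FPKM minimum of 1, and Morc2b, Cd5l and Pcnxl2 are lost at q 0.01. Hipk4, Morc2b, Cd5l and Rbfox1 were also outside the simulation. The reversed genes that it covers therefore do not exceed its maximum of 9 with the larger share. The covariance was -0.00378 against simulated values of -0.0157 and, with the larger share, -0.0313, so both settings gave more negative values than were seen here. Vamp1, Eif2ak2, Stx3, 6330527O06Rik and Rbfox1, 5 genes, were reversed by both isoforms.

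**Figure D3:**
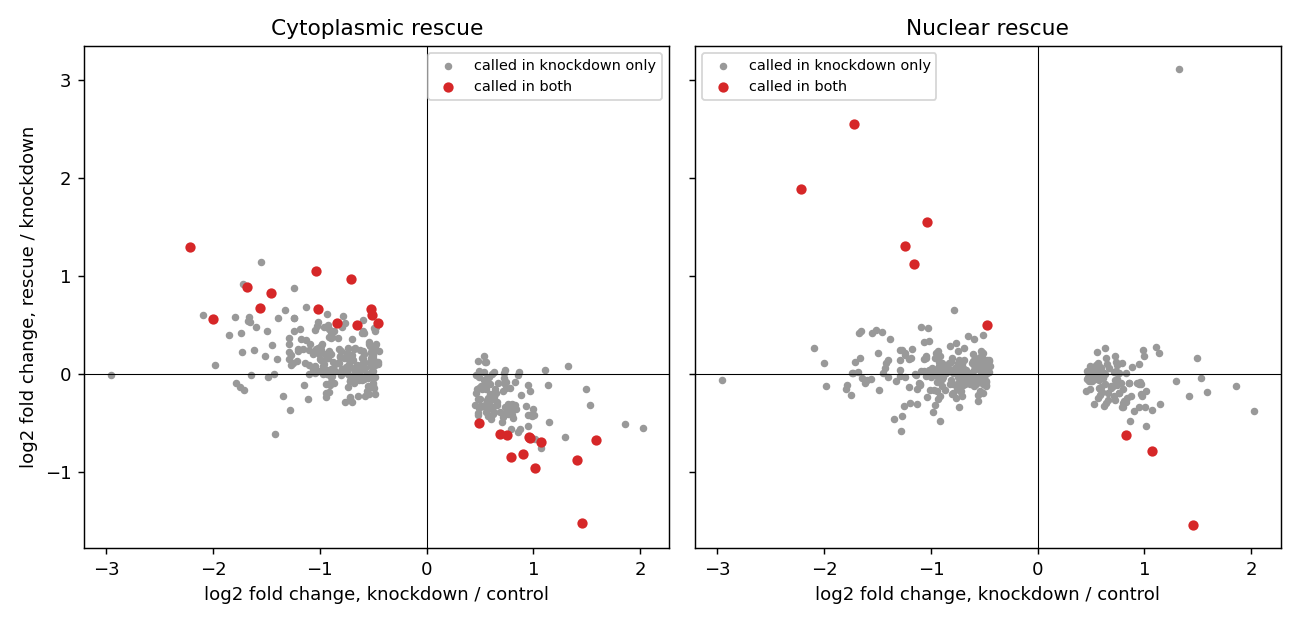
Log2 fold change in each rescue (y axis) against that in the knockdown (x axis) for genes called in the knockdown, without Rbfox1. Red points are called in both tables, 25 for the cytoplasmic and 9 for the nuclear rescue, all in opposite directions.

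A z test of the difference between the cytoplasmic and nuclear rescue, with Benjamini-Hochberg adjustment, called 4 of 15319 genes, with 122 at an unadjusted p below 0.05. Rbfox1, Gm20594 and Iyd were higher with the nuclear isoform and Ptgs2 with the cytoplasmic isoform, at 27.1 against 14.4 FPKM. Adding the error of both tables counts the shared knockdown error in each, which makes the test conservative. With the larger error alone 26 genes passed, among them Nptx2, Inhba, Htr1a and Rbfox2. The small number of calls therefore does not show that the rescues are alike.

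Knockdown changed the inclusion of 214 cassette exons in 202 genes, with 121 less and 93 more included. An exon of Stx3, a syntaxin gene (chromosome 19, 11864538 to 11864583, minus strand), went from an inclusion fraction of 0.563 to 0.102. An exon of mKIAA0787, described in the table as a calmodulin-dependent kinase kinase (chromosome 5, 123186997 to 123187039), went from 0.686 to 0.326. Channel and kinase exons were among the others, in Cacna1a (0.808 to 0.483) and Camk2g (0.352 to 0.137), while those of Kcnd3 (0.466 to 0.743) and Cttn (0.476 to 0.710) were more included. By Fisher's exact test on junction reads 69 of the 214 differed, Stx3 among them (adjusted p = 7.01e-19). Of these 69, 47 were less and 22 more included. For 28 exons the authors' fraction lay over 0.2 from the share of junction reads. The Gria2 exon was one, listed at 0.567 and 0.825 with 98.4% and 96.4% of junction reads including it, and no difference in its junction reads was detected (Fisher's exact adjusted p = 0.403).

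The cytoplasmic isoform changed 150 exons, 89 more and 61 less included, and the nuclear isoform 318, 146 more and 172 less. The mKIAA0787 exon reached 0.657 with the cytoplasmic and 0.813 with the nuclear isoform, and Camk2g 0.410 and 0.599. With the nuclear isoform Eml1 went from 0.125 to 0.470, Camta1 from 0.047 to 0.453, and Mapt from 0.914 to 0.709. An Rbfox2 exon of 40 nt went from 0.782 to 0.573. Fisher's exact test on junction reads passed 31 of the 150, 25 more and 6 less included, and 170 of the 318, 91 more and 79 less included.

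Of exons in the knockdown and cytoplasmic tables, 51 of 51 changed in opposite directions, and for the nuclear table it was 69 of 69. The shared knockdown values favour opposite signs without any effect, and exons that did not change are not in the tables, so no value for chance can be given. With junction reads differing in both tables, 17 and 25 exons remained.

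**Figure D4:**
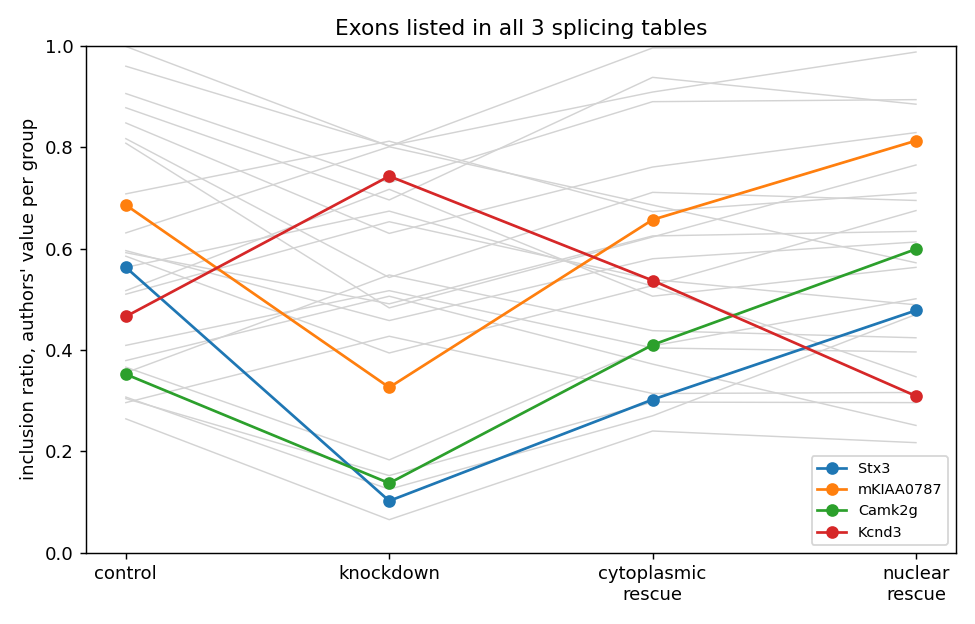
Inclusion fraction (y axis, the authors' value per group, no error bars) in the 4 groups for 27 exons listed in all 3 splicing tables, with Stx3, mKIAA0787, Camk2g and Kcnd3 in colour. Stx3 goes from 0.563 to 0.102 and back to 0.302 and 0.478.

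In 20 of those 27 exons the change was larger with the nuclear than with the cytoplasmic isoform, 74.1% (exact 95% interval 53.7% to 88.9%). Of 45 exons listed for both rescues with the same neighbouring exons, 10 had junction reads that differed between the rescues, including those of Ndrg4, Camta1, Kcnd3, Camk2g and Stx3. The nuclear group also held more Rbfox1 RNA.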

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

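The isoforms differed for 4 genes in a test of the difference itself. Cytoplasmic minus nuclear, the log2 difference was -1.25 for Rbfox1, -1.78 for Gm20594, -1.84 for Iyd and 0.91 for Ptgs2. Junction reads differed between the rescues for 10 exons. Total Rbfox1 FPKM, in which vector and endogenous RNA are not separated, in the nuclear group was 2.38 times that in the cytoplasmic group, so an effect of the isoform and of its amount are confounded throughout.

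Gm20594 and Lars2 were both highest in the nuclear group, and Lars2 was taken up there after its values were seen, while the test below was written before the search. Gm20594 went from 10.4 to 29.5 FPKM and Lars2 from 155 to 1347 FPKM, but Lars2 was not called, since its implied error was 3.04 against 0.325 in the knockdown table. Reads from ribosomal RNA may be assigned to these genes. The longest match of at least 90% identity to an annotated ribosomal RNA was 19 nt for Lars2 and 16 nt for Gm20594, under the 50 nt set before the search as speaking against this. The longest of the 360 sequences searched was 3329 nt, shorter than the complete large-subunit RNA, which was therefore not searched in full, so the earlier reading was not kept and the explanation stays open. No biological explanation was tested.

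The glial pattern was examined with tests chosen after the result was seen. A lower share of neurons would raise the markers of every other cell type. The microglia median was -0.81 and the oligodendrocyte lineage median 0.23. These medians are the pattern itself, so they are no separate test. They show only that a lower share of neurons alone would leave the fall of microglia markers unexplained. Vascular and proliferation markers had medians of 0.20 each and astrocyte markers -0.0033, so a lower share of neurons as a part of the cause is not excluded. The pan-neuronal list had a median of 0.06 at percentile 85.91 of random lists, with 10 members above and 6 below 0. Synaptic vesicle, GABA signalling and channel genes, by contrast, had medians below 0. Loss of Rbfox1 and Rbfox3 in neurons stays open. The called markers moved back by a median of 32.5% in the cytoplasmic and 8.63% in the nuclear rescue. How much of that comes from the shared knockdown values is not known. A difference between culture batches cannot be told apart from the groups, because 0 samples have a column of their own.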

How the results depend on the processing

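Fisher's exact test on junction reads, the same neighbouring exons, and leaving out named genes were alternatives chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per group, and for the same reason leaving out each replicate and the replicate block were not run, nor was the intron motif test. For 98 named gene results, 490 alternatives could end the call: 422 kept it and 68 lost it. Calls lost numbered 24 at q 0.01, 21 with a change of at least 0.5 on log2(FPKM + 1) and 11 with q recomputed from p. They numbered 8 with an FPKM minimum and q recomputed over the genes kept, and 4 with a change of at least 0.5 on log2(FPKM + 0.1). In 66 of the 98 the call was kept by all of these. Centring cannot end a call, and 0 directions turned. At q 0.01 the called genes numbered 238 (knockdown), 41 (cytoplasmic rescue) and 14 for genes reversed by the cytoplasmic isoform. With a change of at least 0.5 on log2(FPKM + 1) there were 217 and 48 in the knockdown and cytoplasmic tables. Recomputing q from p left 49 in the cytoplasmic table. An FPKM minimum with q recomputed over the genes kept left 11 in the nuclear table, where 13 calls met the minimum alone. Moving back by at least 50% with no q in the rescue gave 81 and 18 reversed genes, cytoplasmic and nuclear. With the larger error only, 26 genes differed between the rescues. Exons with a change of at least 0.2 numbered 18, 9 and 48 (knockdown, cytoplasmic, nuclear), and in the upper part of coverage 107, 75 and 159, by construction. Fisher's exact test on junction reads left 69, 31 and 170 exons and 17 and 25 reversed exons. The cause of the other shifts was not tested. Requiring the same neighbouring exons and leaving out Rbfox1, Lars2, Gm20594 and short noncoding genes moved no count beyond 1.5 times.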

Other observations

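Of the motif and short RNA tests below, only that of host genes was chosen after values had been seen. The last count below, of genes moved further back, was not in the plan. Transcripts with TGCATG, the motif bound by Rbfox proteins, in the 3 prime UTR had a slightly lower median change in the knockdown than those without it. Of 11856 genes with a 3 prime UTR, 4725 held the motif. Their median log2 fold change was 0.01 against 0.04 without it, a difference of -0.0246, at percentile 0 of 10000 random sets matched on FPKM and 3 prime UTR length. In the cytoplasmic rescue the difference was 0.0217, at percentile 100, and in the nuclear rescue 0.00613, also at percentile 100. Rbfox1 binding in 3 prime UTRs that raises transcript levels is one hypothesis that meets this, in a test written before the values were seen. General sequence makeup was tested with the 179 other hexamers of the same bases. In the knockdown 1 of them lay lower (percentile 0.559), and in the cytoplasmic rescue 0 lay higher (percentile 100). This argues against the bases of the motif alone as the cause. Matching was on FPKM and 3 prime UTR length only, so other features of the genes that hold TGCATG were not tested. In the nuclear rescue 0 lay higher too. Less the matched random sets, the difference was 0.0295 in the cytoplasmic and 0.00970 in the nuclear rescue, and whether the isoforms differ was not tested. The effect is small, the genes are not independent, and the knockdown values are shared, so the opposite signs are not independent evidence.

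Short noncoding RNA genes, 90 snoRNA, scaRNA and microRNA genes, had a median log2 fold change of -0.21 in the knockdown, with a median implied error of 3.02 and 0 called. Fewer short fragments may be a cause, but 14 other loci of at most 300 nt had a median of -0.0785, between the values set in advance for and against. In the rescues both sets were higher, with medians of 0.25 (short noncoding) and 0.25 (other loci) in the cytoplasmic and 0.21 and 0.23 in the nuclear rescue. The median of 11 host genes was -0.0831 in the knockdown, again between the values set for and against. In the cytoplasmic rescue it was -0.0252 and in the nuclear rescue -0.0173. All rescue values are measured against the same knockdown values, so they decide nothing here, and neither explanation is excluded.

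Of 358 genes called in the knockdown and measured in both rescues, 275 moved further back with the cytoplasmic isoform, 76.8%. The shared knockdown values act on both rescues alike, but genes are not independent and this was not tested. The share covers 172 of 237 fallen and 103 of 121 risen genes. Over genes with FPKM of at least 1, the median change was -0.0573 in the cytoplasmic and -0.0106 in the nuclear rescue, which favours risen genes. Among the exons the change was larger with the nuclear isoform in 20 of 27. Those exons had to be listed in every comparison and these genes called only in the knockdown, so the shares are not directly comparable.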
